A study of Mus musculus with 9 samples.

How the data were processed

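The series held 9 Affymetrix mouse expression arrays from germ-free NMRI-KI mice, a line bred without microbes. They covered the terminal ileum, the caecum and the ascending colon, each from mice left germ-free, mice given Akkermansia muciniphila MucT by the intragastric route in 0.2 ml, and mice given Lactobacillus plantarum WCFS1 by mouth. All mice were female, and the tissues were taken after 7 days of colonisation. Per the labels, the germ-free controls lived in separate isolators. The RNA of 6 mice was pooled for each segment and inoculation, and each pool was labelled from 5 micrograms of total RNA, so that 1 array stood for 1 pool. No inoculation had a replicate array in the same segment.

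The deposited table gave 1 value on a log2 scale for each of 45101 probe sets on each array, 64 of them control probe sets. The scale was not stated in the labels. The highest value was 14.08, which is 17300 on a linear scale if the base is 2 and 1301000 if it is the natural base, where a 16-bit scanner ends at 65536, and base 2 was inferred from this and from the spiked controls. All 9 arrays had the same median, 3.88, so that the authors had scaled them to a common value. The method and software that turned probe intensities into these values, and any background correction, were not given in the sources used here. No array and no column was left out. The number of arrays limits the precision, and no depth of counting applies.

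Probe sets were taken with the gene named for them in the probe table. 34958 were named with 1 gene, 932 with several genes and 9211 with none. The last 2 kinds were not used, so that some known genes were not analysed here although the array may carry probes for them. A symbol that was no gene's current name was replaced through a table of synonyms, and a symbol that was current for any gene was kept as written. 34754 probe sets matched a gene in the annotation table for assembly GRCm38.p6, which was used for names alone. Each of 18194 genes was represented by the probe set with the highest mean over the 9 arrays. For 607 genes that probe set was of a kind known to cross-hybridise and for 954 it was shared within a gene family, which matters most for the defensin, serum amyloid, immunoglobulin, Reg3 and histocompatibility genes.

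Values below the 25th percentile of the table, 1.26, were read as signal that cannot be told from background. Y-linked genes gave a measure of background in these female mice, since 6 of them ranged from -1.89 to 3.62 with a median of 2.15. 17.0% of gene values averaged over the 9 arrays lay below that floor. Where 1 of 2 compared values was below it, the difference was computed against the floor and is given as a lower bound.

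The comparisons, their tests, the gene lists and the rule for naming genes were fixed before the data were examined. Inoculations were compared within each segment as the log2 difference between 2 arrays, with no p-value, because each group was a single pool and the segments of the same mice are not replicates. Genes at least 2-fold apart were counted among those whose higher value was at or above the median of all gene values, 5.25. For each of 31 gene lists holding 583 measured genes, the median log2 difference was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. The shift of a list is its median minus the median of its random lists, and a list was said to stand apart below percentile 2.5 or above percentile 97.5. Counts of list members higher or lower were taken from the plain differences, which keep any offset between the 2 arrays. Random lists draw genes independently, while the genes of a list are often regulated together, so these percentiles overstate how rare a shift is. A gene whose higher value was at or above the expression minimum of 5.25 in each of the 3 segments was also counted when it differed at least 1.5-fold the same way in all 3 segments, beside the number expected if the segments were independent, which segments of the same mice are not. Differences were correlated across genes between segments, and between both bacteria, for which arrays without any change were simulated because the germ-free array is shared.

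Segments were compared with limma, with the 3 pools as a block, an empirical Bayes fit with a mean-variance trend, Benjamini-Hochberg adjusted p-values at 0.05 and a log2 difference of at least 1. The pools carried different inoculations, so their spread includes any effect of the bacteria. Members of the lists were also adjusted over the list alone.

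Named genes followed a rule. For A. muciniphila against germ-free they were the 5 genes furthest up and the 5 furthest down in each segment, and for the other inoculation comparisons 3 of each. For agreement over segments they were, per bacterium, the 5 genes up and the 5 down with the largest of their smallest differences. For ileum against colon they were the 10 genes highest and the 10 lowest among those called and changed the same way in every pool, and for the other segment comparisons 5 of each. For each list described they were up to 4 members with the largest difference that met the expression minimum. Fabp6, Slc10a2, Car1 and Aqp8 were added as a check of the segment labels. Genes named outside this rule are marked as chosen after their values were seen.

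The segment test was tested on simulated data with 200 changed genes. It recovered 99% of the genes changed by 1.5 and 97% of those changed by 3 on the log2 scale, with 5 false calls, and it made 0 calls where nothing was changed. Changes were planted only in genes with a mean at or above the median. The noise was normal and independent, with no effect of the pool, so recovery of genes near background was not tested. Of random lists, 5.11% fell outside the tails, a share that the percentiles set in advance. All lists moved by 0.5 (100%), drawn from genes at or above the median, were called.

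Alternatives were a floor at the 25th percentile, quantile normalisation, equal gene medians, the mean of all probe sets of a gene, other expression minimums and fold thresholds, only list members above the median, and, for segments, no block, each pool left out, 6 arrays in place of 9, only genes above the median, no trend and no minimum difference. Equal medians were set over genes, because the medians over all probe sets were already equal. After seeing the data, 4 more were chosen, namely scaling to the 9 spiked hybridisation controls, segments without the L. plantarum caecum array, agreement over ileum and colon only, and counts without genes at least 8-fold higher in another segment. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.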

Results

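Transcript levels were measured with Affymetrix arrays in 3 gut segments, the terminal ileum, the caecum and the ascending colon, of mice that had been germ-free. The mice either stayed germ-free or carried a single bacterium for 7 days, Akkermansia muciniphila, which lives on intestinal mucin, or Lactobacillus plantarum, a lactic acid bacterium. Each of the 9 arrays held the pooled RNA of 6 mice, so that each segment had 1 array per inoculation and no replicates, and values are given without an error for this reason. The 45101 probe sets of an array yielded 18194 named genes. All arrays had a median of 3.88 on the log2 scale. The number of arrays limits the precision. Spiked hybridisation controls lay 0.36, 0.70 and 0.21 above their mean over the 9 arrays in the germ-free, A. muciniphila and L. plantarum caecum, and between -0.28 and -0.09 in the ileum and colon. The 3' minus 5' difference, a sign of RNA integrity, ranged from 0.30 to 0.54 for Actb and from -0.46 to -0.20 for Gapdh. In the ileum it was 0.30, 0.32 and 0.48 for Actb and -0.46, -0.38 and -0.21 for Gapdh in the germ-free, A. muciniphila and L. plantarum pools. Values under a floor of 1.26 were taken as background, and a fold difference given as at least a number was taken from that floor. Y-linked genes, which these female mice lack, ranged from -1.89 to 3.62, so that the size of a difference from a value under 3.62 is uncertain, and so are those bounds.

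The first question, named in the title of the series, was how A. muciniphila changes immune, tolerance and proliferation genes of the mucosa. S100g, the calcium-binding protein of absorptive cells also known as calbindin-D9k, was higher with A. muciniphila than in germ-free mice in every segment, by 2.04 in the ileum, 1.60 in the caecum and 1.85 in the colon, there from 3.60 (log2, 3.03-fold to 4.11-fold). S100g was at 8.41 in the germ-free caecum and 4.32 in the germ-free ileum, and whether pieces came from the same place in each pool was not tested. In the caecum and colon the markers of B cells and macrophages and the MHC class II genes were higher, in the colon T cell markers were higher too, and 15 of 20 B cell markers were at least 1.5-fold higher there. Among 8529 genes past the expression minimum in every segment, the 4 at least 1.5-fold lower in each were immunoglobulin kappa genes. Igkv6-14 lay at -1.08, -0.71 and -1.17 from ileum to colon, but 1 of the 4, Igk, was higher in the ileum and caecum when all its probe sets were averaged. In the caecum the gene furthest apart among those past the expression minimum was Ang4, a ribonuclease with antimicrobial activity, which was 14.5-fold lower (-3.86).

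Genes at least 2-fold apart numbered 3 higher and 17 lower with A. muciniphila in the ileum, 44 higher and 10 lower in the caecum, and 62 higher and 8 lower in the colon. The balance in the caecum rested on the scaling of the arrays, with 28 higher and 7 lower after quantile normalisation, 24 and 19 with equal gene medians, and 6 and 24 when scaled to the spiked controls. In the colon 177 were higher and 57 lower at 1.5-fold and 128 and 62 with the mean of all probe sets. Without the expression minimum, which adds genes near background, the balance was close to even in the caecum and colon, with 1441 higher and 1336 lower and 1206 and 1083, and the ileum had 945 and 1638. The median of all genes past the expression minimum differed by 0.11 in the caecum, -0.03 in the ileum and -0.05 in the colon. The shifts of gene lists below are relative to random lists that share the offset between arrays.

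Among genes past the expression minimum, those highest in the ileum with A. muciniphila after S100g were Atrn (1.46), which encodes attractin, Kcnip2 (1.00), a potassium channel partner, Ehd2 (0.98), a protein of caveolae, and Plekhm3 (0.97). Kcnip2 and Ehd2 changed sign, to -0.13 and -0.23, when all their probe sets were averaged. The lowest past that minimum were Cyp2c55 (-2.14), a cytochrome P450, Saa1 (-1.99), a serum amyloid, Igkv4-72 (-1.87), Car2 (-1.82), a carbonic anhydrase, and Abcf2 (-1.80), which came to -1.20 with all probe sets averaged. Cyp2c55, Saa1 and Car2 were at 7.10, 8.17 and 6.68 in the germ-free ileum and at 13.1, 12.8 and 12.8 in the germ-free caecum. Large intestine markers as a list lay at -0.20 in the ileum, with Car1, another carbonic anhydrase, at -1.78, and this list no longer stood apart with a floor (-0.00) or after quantile normalisation (-0.08). Whether the ileum pieces of the 3 pools were taken equally close to the caecum was not tested, which bears on these genes.

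In the caecum the highest genes past the expression minimum were Tgfb3 (2.27), which encodes a transforming growth factor beta, Epop (1.86), Cxcl9 (1.86), an interferon-induced chemokine that attracts T cells, S100g and Phf20l1 (1.57). Trpv6, the calcium channel of the same absorptive pathway as S100g and chosen for this comparison after its values were seen, was 1.49 higher. The lowest past that minimum after Ang4 were Rnase2a (-3.16), a ribonuclease of eosinophils, Tcerg1l (-1.30), Ulk3 (-1.24) and Retn (-1.13), the adipocyte hormone resistin. Tgfb3 was at 3.28 without bacteria and Rnase2a at 2.35 with A. muciniphila, both in the range of the Y-linked genes. Averaging all probe sets brought Cxcl9 to 0.81, Phf20l1 to 0.57 and Tcerg1l to -0.66.

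In the colon the highest genes past the expression minimum were Marco, a scavenger receptor of macrophages, at least 16.5-fold higher, Cxcl9 (3.64), Lcp2 (2.64), an adaptor of the T cell receptor, Glycam1 (2.18), a ligand of L-selectin on high endothelial venules, and Reg3a (2.16), an antimicrobial lectin. The lowest past that minimum were Sgsm3 (-1.98), Recql5 (-1.53), a DNA helicase, Igk (-1.40), Hoxb13 (-1.37), a homeobox gene of the posterior gut, and Best2 (-1.22), an anion channel. In the germ-free colon Marco, Cxcl9 and Lcp2 stood at 0.42, 1.63 and 2.77, and Sgsm3 stood at 3.35 with A. muciniphila, all in the range of the Y-linked genes. With the mean of all probe sets Lcp2 came to 0.54, Cxcl9 to 2.52, Igk to -0.54 and Recql5 to -0.69.

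**Figure D1:**
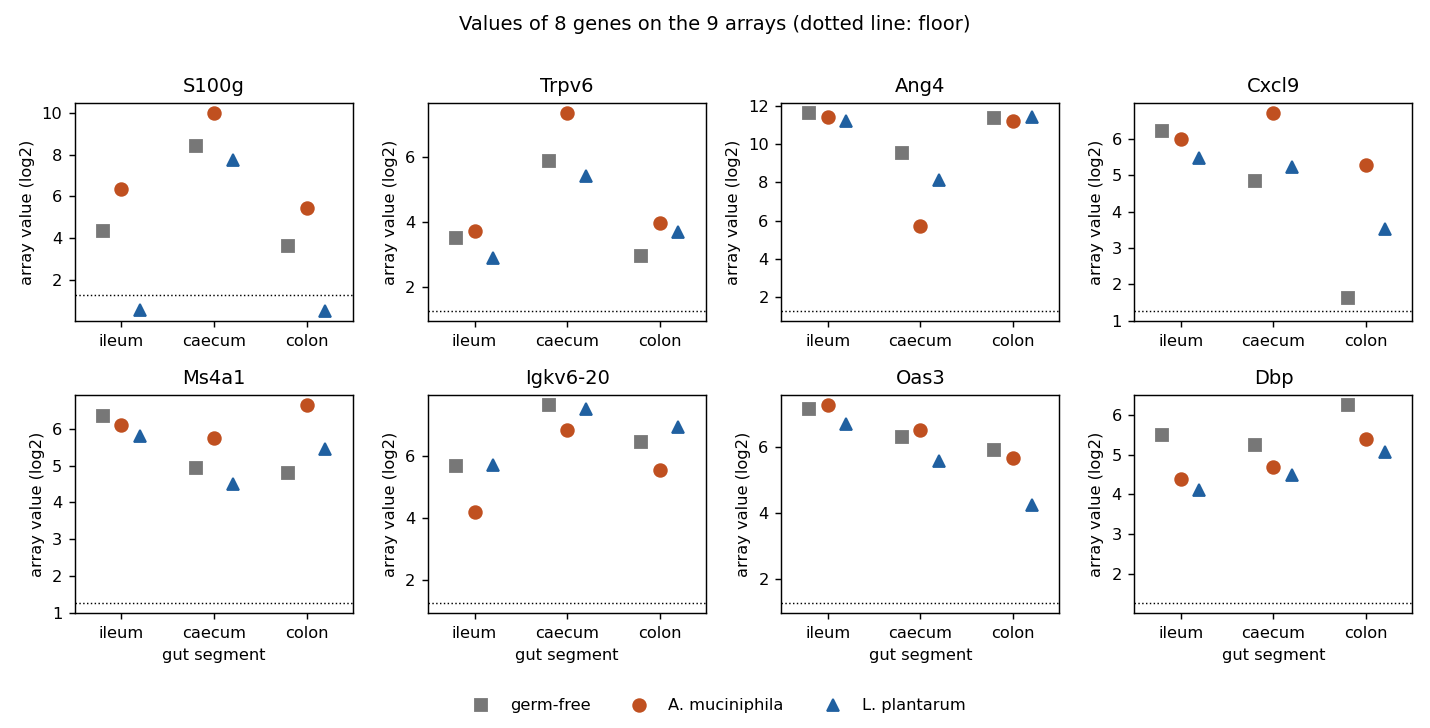
Values (log2, vertical axis) of 8 genes on the 9 arrays, by gut segment on the horizontal axis, with squares for germ-free, circles for A. muciniphila and triangles for L. plantarum, and a dotted line at the floor of 1.26. S100g was highest with A. muciniphila in each segment (6.36, 10.0 and 5.45), while Dbp was highest in the germ-free pool (5.49, 5.25 and 6.26).

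B cell markers shifted by 0.62 in the caecum and 1.07 in the colon and by -0.12 in the ileum, where the list did not stand apart. In the colon 19 of 20 members were higher, among them Ms4a1 (1.85), the surface protein CD20, Cd79a (1.38), a part of the B cell receptor, Ighm (1.37), the constant part of IgM, and Fcmr (1.36), the IgM receptor. In the caecum 11 of the 20 were at least 1.5-fold higher, led by Ltb (1.25), a cytokine of lymphoid tissue, Cd83 (0.90), Ms4a1 (0.81) and Cd79a (0.79). Plasma cell markers shifted by -0.14, 0.05 and -0.03 from ileum to colon, and stood apart in the ileum alone, with Iglv1 at -1.25, Igha, the constant part of IgA, at -0.66 and Jchain at -0.61. That call was lost with a floor (-0.10) and with the mean of all probe sets (-0.06). Igha and Jchain themselves were at least 1.5-fold lower in the colon as well as in the ileum. This held with a floor, each scaling and the mean of all probe sets, and was looked at after the data were seen.

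T and cytotoxic lymphocyte markers shifted by 0.98 in the colon, where 22 of 26 members were higher, with Ccl5 (2.14), a chemokine of cytotoxic cells, Cd3d (1.59) and Cd3g (1.33), chains of the T cell receptor complex, and Cd28 (1.37), its co-stimulatory partner. The shift of 0.47 in the caecum, with Cd7 at 1.27 and Cd3d at 0.86, was no longer apart with a floor (0.23) or with members above the median only (0.09). Macrophage, dendritic cell and granulocyte markers shifted by 0.31 in the caecum and 0.35 in the colon, with Lyz2, the lysozyme of macrophages, at 0.59 and 0.91. MHC class II genes shifted by 0.23 and 0.69, and all 14 members were higher in the colon, such as H2-Oa (1.14), H2-DMb2 (0.82) and Cd74 (0.71), the invariant chain. Complement genes shifted by 0.23 and 0.28, with Cfp, properdin, at 1.15 in the caecum and 0.69 in the colon. MHC class I genes shifted by 0.09 in the colon, a call that was lost with the mean of all probe sets (0.06) and with members above the median only (0.04).

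The interferon response list shifted by 0.16 in the caecum and 0.13 in the colon, with 27 and 22 of 31 members higher, led by Cxcl9 in both and by Ifit2 (0.90) and Gbp6 (0.67) in the caecum. The median of all genes past the expression minimum differed by 0.11 and -0.05, an offset that these counts of members keep. Epithelial defence genes shifted by -0.18 in the ileum, where 8 of 27 members were higher, and by 0.12 in the caecum and 0.10 in the colon. Reg3g and Reg3b, antimicrobial lectins, were 1.25 and 1.00 higher in the caecum and 0.86 and 1.04 higher in the colon, beside Ang4 at -3.86 in the caecum. The call in the caecum was lost with a floor, after quantile normalisation and with members above the median only (0.08, 0.05 and 0.02), and the call in the colon with members above the median only (0.06). Paneth cell markers lay at -0.15 in the ileum, with 0 of 8 members higher, a call lost after quantile normalisation (-0.11) and with the mean of all probe sets (-0.11).

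Tolerance and regulation genes shifted by 0.21 in the caecum, where 11 of 28 members were at least 1.5-fold higher, among them Tgfb3 (2.27) and Cd274 (0.77), the ligand PD-L1, while Aldh1a2, which makes retinoic acid, and Ikzf2 were higher by less, 0.47 and 0.35. Members above the median gave -0.10, so that the direction rested on weakly expressed members, and the list did not stand apart in the ileum (-0.03) or colon (0.12). Cell cycle genes shifted by 0.12 in the colon with 0 of 39 members at least 1.5-fold higher, and with Melk at 0.31, Ccna2 at 0.24, Rrm1 at 0.22 and Mcm7 at -0.21. This call was lost with the mean of all probe sets (0.06), and the list did not stand apart in the ileum (-0.03) or caecum (0.01). Stem cell and Wnt target genes lay at -0.18 in the colon, with Rnf43 at -0.46 and Ascl2 at -0.40, and no longer stood apart with a floor (-0.11), with the mean of all probe sets (-0.15) or with members above the median only (-0.05).

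Among metabolic lists, cholesterol synthesis genes lay at -0.14 in the caecum, with Srebf2, their transcription factor, at -0.29 and Insig1 at 0.20. In the colon PPAR targets shifted by 0.09, with Angptl4 (1.27), an inhibitor of lipoprotein lipase, Cd36 (0.55), a fatty acid transporter, and Pdk4 (0.48), and bile acid and lipoprotein genes shifted by 0.20 with Apoa1 at 1.01, a call lost with a floor (0.07). Enteroendocrine markers shifted by 0.33 in the caecum, where Insl5 (1.12), Nts (0.65), Chga (0.51) and Gcg (0.47), a set of gut hormones and the granule protein chromogranin A, were higher.

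Markers of other tissues also differed between the same arrays. Fibroblast markers shifted by 0.19, 0.31 and 0.31 from ileum to colon, with Col1a1 at 0.93 in the caecum, smooth muscle markers by 0.28, 0.15 and -0.06, with Myh11 at 0.43 in the ileum, and enteric neuron markers by 0.28 in the ileum. Adipocyte markers lay at -1.04 in the ileum and -0.53 in the caecum and at 0.38 in the colon, where Adipoq, adiponectin, was at -1.49, -0.93 and 0.41. Exocrine pancreas markers shifted by 0.56 in the colon, with Prss2 at 0.76 and by -0.44 in the caecum, where the median of its members was 0.32 without bacteria and 0.20 with A. muciniphila, under the floor of 1.26. The fibroblast shift in the caecum (0.02), the neuron shift (0.08) and the pancreas shift in the caecum (-0.22) were lost with the mean of all probe sets, the neuron shift also with members above the median only (0.13), and the pancreas shift also with a floor (-0.11).

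**Figure D2:**
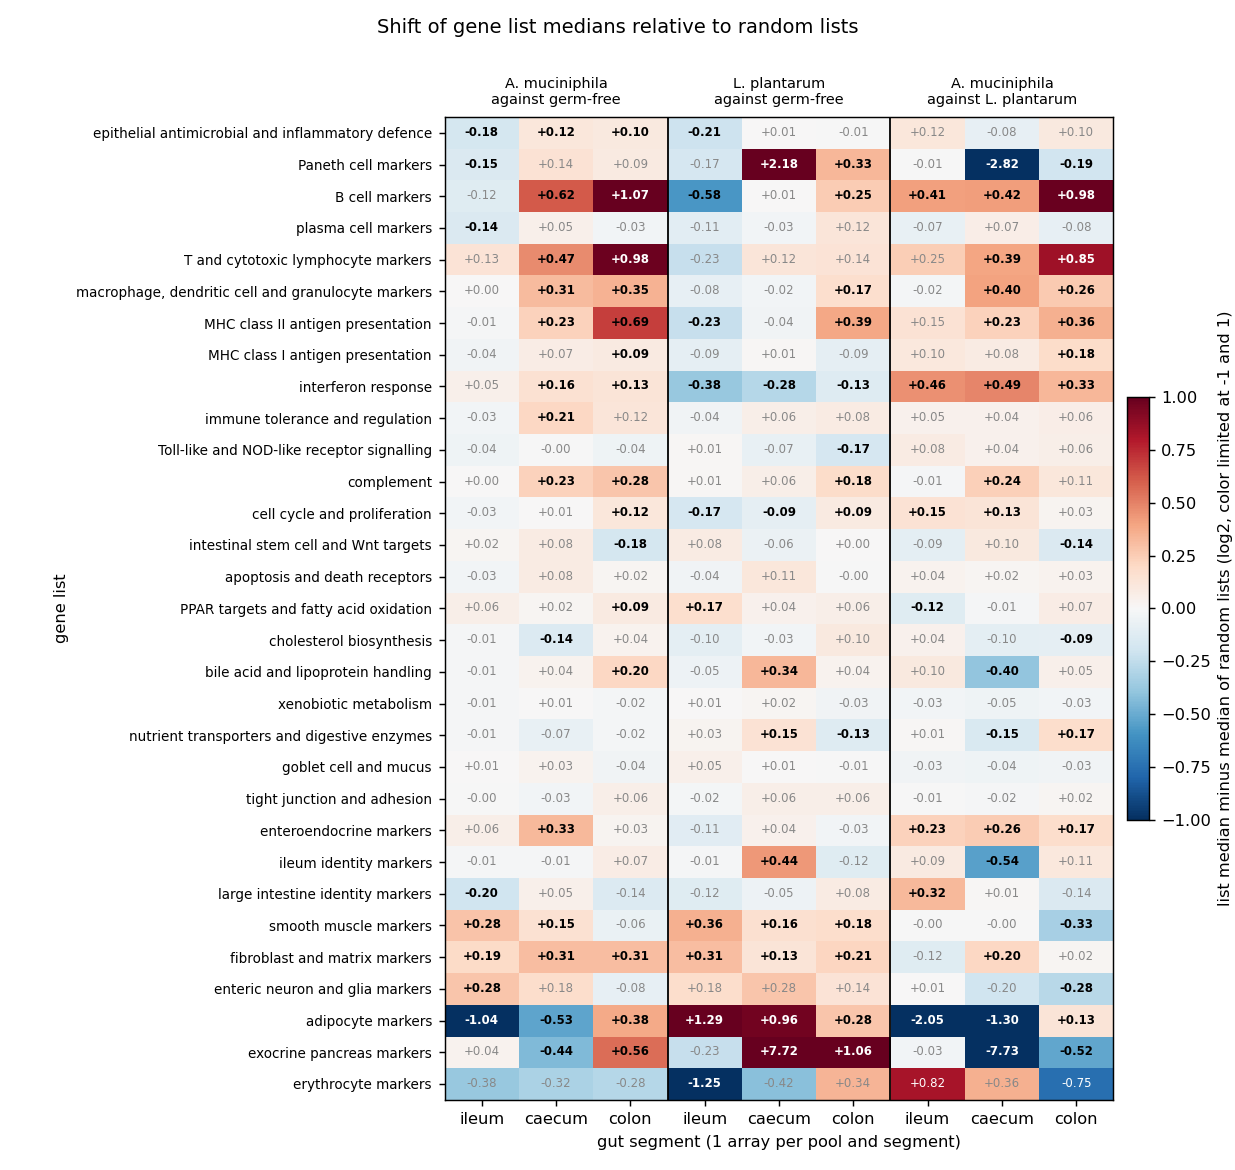
Shift of the median log2 difference of each of 31 gene lists (vertical axis) relative to random lists of matched expression, by gut segment within each inoculation comparison (horizontal axis), with red for higher, blue for lower and bold print where a list stood apart. B cell markers shifted by -0.12, 0.62 and 1.07 with A. muciniphila against germ-free, and the interferon response by 0.46, 0.49 and 0.33 with A. muciniphila against L. plantarum.

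Across segments, of 8529 genes past the expression minimum in each, 1 gene (S100g) was at least 1.5-fold higher with A. muciniphila in all 3 segments and 4 genes (Igk, Igkv14-111, Igkv6-14 and Igkv6-20) were lower. Independent segments would give 0.00603 and 0.000745, but the segments came from the same mice, so these are not the numbers for no change in this design. With the mean of all probe sets 5 genes were higher, namely S100g, Ifnar2, Met, Ppp1r1a and Smarca1, and 7 were lower, namely Igkv14-111, Igkv5-39, Igkv6-14 and Igkv6-20 and, outside the immunoglobulins, Ccdc116, Prkacb and Spata13, the genes new to this setting being named after their values were seen. The other genes with the largest agreement were Arsj, a sulfatase (0.56 or more in each segment), Akr1e1, an aldo-keto reductase (0.51 or more), Cxcl10, a chemokine induced by interferon (0.50 or more), and Dock10 (0.43 or more), and on the lower side Dbp, a transcription factor of the circadian clock (-1.10, -0.57 and -0.87). Igkv6-20 lay at -0.83 in the caecum and -0.88 in the colon, and Igkv14-111 at -0.90, -0.66 and -0.99. With all probe sets averaged, Igk was at 0.21 in the ileum and 0.93 in the caecum, and Dock10 at -0.01 in the caecum, so that their direction there depended on the probe set, while Dbp came to -2.30 in the caecum and -1.99 in the colon.

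Differences with A. muciniphila correlated across genes at 0.14 between ileum and caecum, -0.000913 between ileum and colon and 0.25 between caecum and colon (Pearson, 9026 genes, which are not independent replicates). Spearman coefficients were 0.13, -0.03 and 0.23. With all probe sets averaged the value for caecum and colon was 0.14.

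The second question was how L. plantarum compares with the germ-free state. The interferon response list lay lower in every segment, at -0.38 in the ileum, -0.28 in the caecum and -0.13 in the colon, with 2, 2 and 5 of 31 members higher. The median of all genes past the expression minimum also lay lower, at -0.09, -0.21 and -0.10, an offset that these counts of members keep. In the ileum Usp18 (-1.07), which restrains interferon signalling, Irgm1 (-1.07), an immunity-related GTPase, and Ifit1 (-0.99) were lower. In the caecum Zbp1 (-0.96), a sensor of nucleic acids, Oasl2 (-0.81), Rtp4 (-0.75) and Oas2 (-0.73) were lower, and in the colon Oas3 (-1.67), Gbp6 (-0.83), Ddx58 (-0.57), which encodes the RNA sensor RIG-I, and Oasl2 (-0.55). In the caecum, transcripts of digestive enzymes of the pancreas were far higher than in the germ-free array.

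Genes at least 2-fold apart numbered 43 higher and 48 lower in the ileum, 59 and 43 in the caecum, and 14 and 22 in the colon. The balance rested on scaling in the ileum, with 51 higher and 39 lower after quantile normalisation, 47 and 45 with equal gene medians and 95 and 17 when scaled to the spiked controls. In the caecum it was 58 and 26, 64 and 23, and 67 and 11 with these scalings, and in the colon 20 and 24, 17 and 20, and 20 and 26. The direction also turned with the thresholds, since the caecum had 142 higher and 384 lower at 1.5-fold, 177 and 225 with the mean of all probe sets and 1097 and 1792 without an expression minimum. The colon had 1293 and 1101 without the minimum and 8 and 3 with the 75th percentile as minimum. Without genes at least 8-fold higher in another segment, the caecum had 16 higher and 42 lower, since 43 of the 59 higher genes were left out. The median of all genes past the expression minimum differed by -0.21 in the caecum, -0.09 in the ileum and -0.10 in the colon.

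In the ileum the highest genes past the expression minimum were Mrap (4.10), a melanocortin receptor partner found in fat cells, Hp (3.87), haptoglobin, and Pnpla3 (2.25), a lipid hydrolase of liver and fat. Adipocyte markers shifted by 1.29 on the same arrays, with Car3 at 1.33, Retn at 1.32 and Adipoq at 1.29, and by 0.96 in the caecum and 0.28 in the colon. The lowest genes past the minimum were Car1, at least 774-fold lower, Cyp2c55, at least 57.3-fold lower, and Saa1 (-5.31). The unknown distance of the ileum pieces from the caecum applies here too. Car1 was at 10.9 in the germ-free ileum and at -4.29 with L. plantarum, and at 13.8 and 13.4 in the caecum of the same pools. PPAR targets shifted by 0.17 in the ileum, with Cd36 at 1.20, Pdk4 at 1.05 and Acaa1b at 1.00, a call lost after quantile normalisation (0.15). Mrap and Hp stood at 1.49 and 2.16 in the germ-free ileum and Saa1 at 2.85 with L. plantarum, all in the range of the Y-linked genes. With all probe sets averaged Mrap was at 1.41 and Saa1 at -6.07.

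The L. plantarum and germ-free ileum arrays also differed in the 3' minus 5' values of Actb (0.48 against 0.30) and Gapdh (-0.21 against -0.46), and whether this moved the ileum lists was not tested. B cell markers lay at -0.58 in the ileum, where 0 of 20 members were higher, with Cd79a and Cd79b, the signalling chains of the B cell receptor, at -0.71 each, and at 0.01 in the caecum and 0.25 in the colon, where 11 of 20 members were higher, 3 of them at least 1.5-fold, and 4 were at least 1.5-fold lower, with Ms4a1 at 0.64. MHC class II genes lay at -0.23 in the ileum, with H2-Oa at -0.49, and at 0.39 in the colon, with H2-Oa at 0.78. The ileum call was lost after quantile normalisation (-0.17), with the mean of all probe sets (-0.09) and with members above the median only (-0.19). Macrophage markers and complement genes shifted by 0.17 and 0.18 in the colon, with 17 of 28 and 9 of 13 members higher and with C1qb, a part of complement C1, at 0.28, and the complement call was lost with the mean of all probe sets (0.14).

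Cell cycle genes lay at -0.17 in the ileum, -0.09 in the caecum and 0.09 in the colon, with 0 of 39 members at least 1.5-fold apart in any segment, and with Ccne1 at -0.57 and Cdk1 at -0.54 in the ileum. All 3 of these calls were lost with the mean of all probe sets (-0.12, -0.04 and 0.08). Epithelial defence genes lay at -0.21 in the ileum, where Saa1 led and Reg3a was at -0.44, a call lost after quantile normalisation (-0.16). Toll-like and NOD-like receptor genes lay at -0.17 in the colon, with Nod1, a sensor of bacterial peptidoglycan, at -0.44, and nutrient transporter genes at -0.13, with Enpep at -0.62. Both of these colon calls were lost with a floor (-0.06 each) and with members above the median only (-0.03 and -0.08). The 4 erythrocyte markers lay at -1.25 in the ileum and no longer stood apart with a floor (-0.26) or with the mean of all probe sets (-0.46).

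In the caecum the highest genes past the expression minimum were Cpa1, Cela2a and Cpb1, digestive enzymes of the exocrine pancreas, at least 134-fold, 287-fold and 114-fold higher. The pancreas list shifted by 7.72, and by 6.80 with a floor, since the median of its members was under the floor in the germ-free caecum, and all of its 10 members were at least 1.5-fold higher. Paneth cell markers shifted by 2.18 on the same array, with Defa31, an alpha-defensin, at 9.72, Itln1 at 2.68, Lyz1, the lysozyme of Paneth cells, at 1.23 and Ang4 at -1.45. Ileum markers shifted by 0.44, bile acid and lipoprotein genes by 0.34 and nutrient transporter genes by 0.15, with Fabp6, the ileal bile acid binding protein, at 4.06, Apoa1 at 2.22, Anpep at 3.08 and Slc6a19, an amino acid transporter, at 2.89. The lowest genes past the expression minimum were Madcam1 (-2.36, to 3.12), the vascular ligand of gut-homing lymphocytes, Ribc2 (-1.63) and Rnase2a (-1.56).

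In the colon the highest genes past the expression minimum were Trim62 (2.07, from 3.26), Ctrc (1.62), a pancreatic chymotrypsin, and Angptl4 (1.49), which was at -0.61 with all probe sets averaged. The pancreas list shifted by 1.06 in the colon, with Cela3b at 1.49, and Paneth cell markers by 0.33, with Pnliprp2, a pancreatic lipase relative, at 0.49 and Lyz1 at 0.30. The lowest past that minimum were Slc37a2 (-2.77), a sugar phosphate transporter, Reg4 (-2.39), a lectin of the Reg family, and Il18bp (-1.92), which binds and blocks interleukin 18. Over the pools Slc37a2 was 5.68 higher in the caecum than in the colon. Hoxb13 stood at 4.33, 5.70 and 6.38 in the A. muciniphila, germ-free and L. plantarum colon. Whether the colon pieces of the 3 pools came from the same place was not tested, which bears on Slc37a2 and Hoxb13. Fibroblast markers shifted by 0.31, 0.13 and 0.21 from ileum to colon and smooth muscle markers by 0.36, 0.16 and 0.18, with the fibroblast call in the caecum lost with the mean of all probe sets (0.10).

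**Figure D3:**
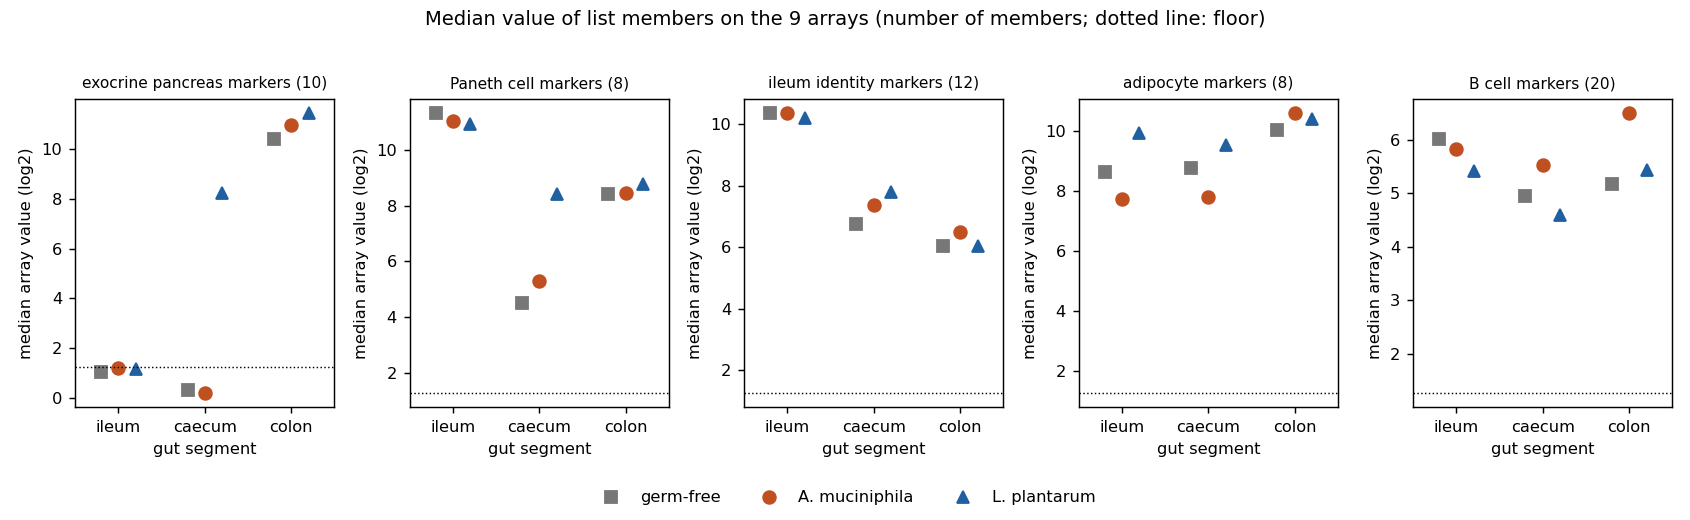
Median value (log2, vertical axis) of the members of 5 lists on the 9 arrays, by gut segment on the horizontal axis, with squares for germ-free, circles for A. muciniphila and triangles for L. plantarum and a dotted line at the floor of 1.26. Pancreas markers stood at 8.21 in the L. plantarum caecum against 0.32 and 0.20 in the germ-free and A. muciniphila caecum, and between 10.4 and 11.4 in the colon.

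With L. plantarum 3 of 8548 genes past the expression minimum in each segment were at least 1.5-fold higher and 7 lower in all 3 segments. The higher genes included the Riken entry C730049O14Rik, which the naming rule skips. Of the others, those with the largest agreement on the higher side were Slpi, a protease inhibitor of mucosal secretions (1.30, 1.00 and 0.63), Pygl, a glycogen phosphorylase (0.97, 0.67 and 0.63), Rnf125, a ubiquitin ligase (0.71, 0.57 and 0.56), Klhl24 and Zeb2. Those on the lower side were Smim27 (-1.16, -1.44 and -1.10), Cdc42ep2, an effector of Cdc42 (-0.85, -1.02 and -0.97), Dbp (-1.38, -0.77 and -1.19), Gsdmc2, a gasdermin (-1.84, -0.75 and -1.34), and Trim15 (-0.95, -0.73 and -0.60). Dbp came to -0.19 in the caecum and -2.17 in the colon with all probe sets averaged. After quantile normalisation 5 genes were higher and 1 lower, so that the balance depended on scaling. Differences correlated across genes at 0.19 between ileum and caecum, 0.13 between ileum and colon and 0.18 between caecum and colon, with Spearman coefficients of 0.33, 0.10 and 0.19.

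Differences from germ-free with either bacterium correlated at 0.54 in the ileum, 0.39 in the caecum and 0.55 in the colon. Because both use the same germ-free array, unchanged arrays simulated with the measured spread gave 0.47, 0.49 and 0.49. The simulation gave each array the same spread per gene, so that it centres on 0.50, and its departures from that are noise of the simulation. In the ileum the measured and simulated values were 0.52 and 0.53 with a floor and 0.47 and 0.52 with the mean of all probe sets. In the colon both were 0.50 with the mean of all probe sets. Differences of this size are not resolved, so that no agreement beyond the shared array was established in any segment. Dbp was among the genes of largest agreement with both bacteria.

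The third comparison set both bacteria against each other, without the germ-free array. Interferon response genes were higher with A. muciniphila in every segment, by a shift of 0.46 in the ileum, 0.49 in the caecum and 0.33 in the colon, and 30 of 31 members were higher in each. These counts keep the offset between the arrays, since the median of all genes past the expression minimum differed by 0.07, 0.31 and 0.05. In the caecum most genes were thus higher, and the count says little there beyond the shift. In the caecum Cxcl9 led the list, before Zbp1 (1.39), Igtp (1.34), an interferon-inducible GTPase, and Cxcl10 (1.18), and in the ileum Ifit1 (1.17), Irgm1 (1.08), Usp18 (1.07) and Cxcl10 (1.06). In the colon Cxcl9 (1.75), Oas3 (1.44), Cxcl10 (0.98) and Gbp6 (0.90) led it. B cell markers shifted by 0.41, 0.42 and 0.98 from ileum to colon, with Ltb at 0.78 and 1.38 in the ileum and caecum and Cr2, a complement receptor of B cells, at 1.38 in the colon.

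S100g was at least 34.3-fold higher with A. muciniphila than with L. plantarum in the ileum, 2.28 higher in the caecum and at least 18.2-fold higher in the colon. Trpv6 (1.93) and Gsta3 (1.98), a glutathione transferase, were also higher in the caecum, Car1, at least 226-fold, and Saa1 (3.32) in the ileum, and Marco (3.32) and Reg4 (2.26) in the colon. Genes lower with A. muciniphila were Hp, at least 27.4-fold, Mrap, at least 20.1-fold, and Amy1 (-3.90), an amylase, in the ileum, Cela2a, Cpa1 and Cpb1, at least 287-fold, 134-fold and 114-fold, in the caecum, and Hoxb13 (-2.05), Igk (-1.58) and Trim62 in the colon. With L. plantarum Saa1 in the ileum and Marco in the colon stood at 2.85 and 1.98, and with A. muciniphila Amy1 stood at 2.19, in the range of the Y-linked genes. Mrap came to -2.10 and Igk to -0.32 with all probe sets averaged.

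T cell markers shifted by 0.39 in the caecum and 0.85 in the colon, with Cd3d at 1.13 and 1.22, and the caecum call was lost with a floor (0.21) and with members above the median only (0.12). Macrophage markers shifted by 0.40 and 0.26 in these segments, with Lyz2 at 0.71 in the colon and C1qb at 0.90 in the caecum, MHC class II genes by 0.23 and 0.36, with Cd74 at 0.81 and 0.50, and complement genes by 0.24 in the caecum. MHC class I genes shifted by 0.18 in the colon, with H2-Q2 at 0.56. Cell cycle genes shifted by 0.15 in the ileum and 0.13 in the caecum, with Birc5, survivin, at 0.48 in the ileum and Plk1, a mitotic kinase, at 0.69 in the caecum, where the call was lost with the mean of all probe sets (0.06). Enteroendocrine markers shifted by 0.23, 0.26 and 0.17, with Nts, neurotensin, at 0.52, 0.75 and 0.78, but the colon value was -0.04 with a floor.

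Paneth cell markers lay at -2.82 in the caecum, with Defa31 at -6.78, and at -0.19 in the colon, with Itln1 at -0.39, while ileum markers lay at -0.54, bile acid and lipoprotein genes at -0.40 and nutrient transporter genes at -0.15 in the caecum, where the pancreas list lay at -7.73, and at -6.73 with a floor. In the colon the pancreas list lay at -0.52 and nutrient transporter genes at 0.17, with Enpep at 0.57, a call lost with a floor (0.02). Stem cell and Wnt target genes lay at -0.14 in the colon, with Ascl2 at 0.70 and Lrig1 at -0.31, and cholesterol synthesis genes at -0.09, with Sqle at -0.18, and both calls were lost with the mean of all probe sets (-0.03 and -0.06), the first also with a floor (-0.11). Large intestine markers shifted by 0.32 in the ileum, led by Car1, and lay at -0.08 with a floor and 0.01 with the mean of all probe sets, and PPAR targets lay at -0.12 there, with Cd36 at -2.19, a call lost with a floor (-0.09) and after quantile normalisation (-0.10).

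Adipocyte markers were at -2.05 in the ileum, -1.30 in the caecum and 0.13 in the colon, with Adipoq at -2.77 in the ileum, and the colon call was lost with the mean of all probe sets and with members above the median only (0.11 each). Fibroblast markers shifted by 0.20 in the caecum, with Col1a1 at 1.22, a call lost with the mean of all probe sets (0.02), and smooth muscle and enteric neuron markers lay at -0.33 and -0.28 in the colon, with Des, desmin, at -0.46 and Prph at -0.94, and the neuron call was lost with the mean of all probe sets (-0.30). Xenobiotic metabolism, goblet cell and mucus, tight junction, and apoptosis genes did not stand apart in any of the 9 comparisons of inoculations. Their shifts with A. muciniphila against germ-free in the colon were -0.02, -0.04, 0.06 and 0.02, and Muc2, the main secreted mucin and chosen after its values were seen, differed by 0.16, 0.17 and 0.01 from ileum to colon.

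Genes at least 2-fold apart between both bacteria numbered 34 higher and 45 lower with A. muciniphila in the ileum, 69 and 61 in the caecum, and 40 and 12 in the colon. The balance in the caecum rested on scaling, with 34 and 62 after quantile normalisation, 27 and 78 with equal gene medians and 7 and 111 when scaled to the spiked controls. In the ileum it was 32 and 49, 36 and 48, and 18 and 86 with these scalings. It also rested on the thresholds, with 834 higher and 105 lower in the caecum at 1.5-fold against 6 and 41 at 3-fold, 213 and 138 in the ileum at 1.5-fold, and 1111 and 1159 in the colon without an expression minimum. Without genes at least 8-fold higher in another segment the caecum had 69 higher and 22 lower. The median of all genes past the expression minimum differed by 0.31 in the caecum. Among genes past the expression minimum, 10 were at least 1.5-fold higher and 2 lower in all 3 segments, a balance that turned with scaling, with 6 and 3 after quantile normalisation, 5 and 3 with equal gene medians and 3 and 5 when scaled to the spiked controls. Differences correlated at 0.18, 0.16 and 0.07 between ileum and caecum, ileum and colon, and caecum and colon, with Spearman coefficients of 0.25, 0.18 and 0.11. Across all 31 lists and 9 inoculation comparisons 107 of 279 values stood apart, where lists of independent genes would give 13.95. Members of a list are often regulated together, lists share genes and the comparisons share arrays, so 13.95 is not the number for no change here.

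The segments themselves were compared over the 3 pools with limma, which checks the tissue labels and gives the level of each gene in the pieces taken. Its SE and p-values use a spread taken over all 9 arrays and partly shared over genes. They thus do not measure the spread of a gene over the 3 pools of a segment, which for Slc10a2 was an SD of 0.49 in the ileum and 0.25 in the colon. Fabp6 averaged 13.1 in the ileum and was under the floor in the colon (log2 difference of at least 11.8, adjusted p = 1e-11, n = 3). Slc10a2, the ileal bile acid transporter, was 1.54 ± 0.17 (SE, n = 3) higher in the ileum than in the colon, in 3 of 3 pools (adjusted p = 2.32e-06) and 1.75 ± 0.17 higher than in the caecum (adjusted p = 4.03e-07). Aqp8, a water channel of the large intestine, was lower in the ileum than in the colon, with a log2 difference of -8.60 or beyond (adjusted p = 3.68e-10), and between caecum and colon it differed by 1.27 ± 0.52 without passing the test (adjusted p = 0.0641, and between 4.95e-18 and 0.514 over the alternatives). It passed without the germ-free pool (1.31, adjusted p = 0.00251) and without the L. plantarum pool (1.57, adjusted p = 0.00126). Car1 averaged 5.22 ± 8.28 (SD, n = 3) in the ileum against 12.9 ± 0.10 in the colon (adjusted p = 0.00547), and this call was lost with a floor (adjusted p = 0.124) and without a trend (adjusted p = 0.157), the range over the alternatives starting at 2.22e-08 without the L. plantarum pool, where the log2 difference was -3.0.

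Between ileum and colon 1196 genes were higher and 1162 lower in the ileum, and the balance rested on scaling, with 1076 and 1277 after quantile normalisation and 1008 and 1351 when scaled to the spiked controls. The genes furthest higher were Defa31, Lgals2, a galectin, Defa39, Fabp6, Bcl2l15, Rdh7, a retinol dehydrogenase, Pdzk1, a scaffold of transporters, Olfm4, a marker of crypt stem cells, Cyp3a25 and Apoa4, an apolipoprotein, each with a log2 difference of at least 7.84. Those furthest lower were the pancreatic enzymes Cpa1, Cela2a, Ctrl, Cpb1, Ctrc, Prss2 and Ctrb1, and Lpo, lactoperoxidase, St6galnac6, a sialyltransferase of mucins, and Cd177. The pancreas list had medians from 10.4 to 11.4 on the colon arrays. Whether pancreas tissue was taken along with the colon was not tested, so these enzymes need not mark the colon itself. Of the lists, 17 of 31 interferon response genes were higher in the ileum and 0 lower, such as Cxcl9 (2.41 ± 0.45, SE), Rsad2 (1.99 ± 0.11) and Ifit3 (1.87 ± 0.12). Bile acid and lipoprotein genes were higher in 17 of 21, with Npc1l1, the sterol transporter (7.72 ± 0.41), and nutrient genes in 16 of 23, with Anpep, a peptidase of the brush border (8.88 ± 0.61), and Slc6a19 (6.36 ± 0.42).

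Goblet cell and mucus genes were lower in the ileum in 13 of 31, among them Tff2, a trefoil peptide, and Fut2, a fucosyltransferase, which were under the floor on every ileum array and at 8.02 or more and 6.79 or more on the colon arrays. Large intestine markers were lower in 10 of 13, with Hoxb13 under the floor in the ileum and between 4.33 and 6.38 in the colon. Adjusted over the list alone, the counts were 17 higher for interferon response genes, 17 higher for bile acid genes, 16 higher for nutrient genes, 13 lower for goblet genes and 10 lower for large intestine markers.

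Between caecum and colon 1129 genes were higher and 674 lower in the caecum. Genes furthest higher were Defa31, Lgals2, Fabp6, Gal3st2c and Slc37a2 (5.68 ± 0.60, SE), and those furthest lower were Cpa1, Ctrl, Cela2a, Cpb1 and Rnase1, all enzymes of the pancreas, with log2 differences of -7.14 or beyond. Defa31 averaged 6.16 ± 4.98 (SD, n = 3) in the caecum, with 1.95, 4.88 and 11.7 in the germ-free, A. muciniphila and L. plantarum pools, and its log2 difference from the colon, where it was under the floor, was at least 4.90. Without the L. plantarum caecum array the difference fell from 11.3 to 8.28, both measured from colon values under the floor, and the call stayed (adjusted p = 7.27e-08). The size of the difference thus rested in part on that array. Defa31 lost its call with a floor (adjusted p = 0.164, the highest of the alternatives, the lowest being 8.55e-49 with 6 arrays). The fit of 6 arrays leans on a spread shared over genes, so this lowest value does not measure the spread of Defa31 over the 3 pools. Of xenobiotic metabolism genes, 18 of 31 were higher in the caecum, with Cyp1a1, a cytochrome P450 (2.29 ± 0.19), and Ces1g, a carboxylesterase (2.03 ± 0.10), and of cell cycle genes 16 of 39, with Bub1b (1.65 ± 0.18) and Rrm2 (1.39 ± 0.11). The list medians, 1.20 and 0.94, were 0.51 and 0.25 when scaled to the spiked controls, against 0.35 and -0.34 for all genes. All 10 pancreas markers and all 8 adipocyte markers were lower, with Retn at -1.74 ± 0.35. Whether pancreas and fat tissue lay in the colon pieces was not tested, so these differences need not belong to the gut wall. Adjusted over the list alone, 18 xenobiotic and 17 cell cycle genes were higher and 10 pancreas and 8 adipocyte markers lower. The count of genes higher in the caecum rested on scaling, with 491 higher and 757 lower after quantile normalisation and 164 and 2109 when scaled to the spiked controls, and it was 1475 higher and 646 lower without the L. plantarum pool and 657 and 565 without the A. muciniphila pool.

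Between ileum and caecum 1087 genes were higher and 1853 lower in the ileum. Naaladl1, a peptidase of the ileum, Cyp3a25, Defa39, Apoa4 and Reg3a were furthest higher, and Slc37a2, Aqp8, St6galnac6, Cyp2d10 and Gal3st2c furthest lower, with log2 differences of -5.19 or beyond. Paneth cell markers were higher in the ileum in 6 of 8, with Mmp7, which activates defensins (8.03 ± 0.54, SE), and Itln1 (5.40 ± 0.36), and 16 of 31 xenobiotic genes were lower. The list median of the xenobiotic genes, -1.09, was -0.47 after quantile normalisation and -0.51 when scaled to the spiked controls, against -0.28, -0.08 and 0.30 for all genes. Adjusted over the list alone, 6 Paneth genes were higher and 16 xenobiotic genes lower. Scaling to the spiked controls gave 2456 higher and 668 lower, and quantile normalisation 1256 and 1324.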

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

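All tests of explanations in this part were chosen only after the result was seen, except the splits of the arrays, which were planned.

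The first pattern weighed was the set of pancreas and small intestine transcripts in the L. plantarum caecum array. If exocrine pancreas tissue was in that caecum pool, pancreas genes would keep a constant ratio to the colon arrays, which also held them, and all 10 list members were above the floor with a median of -2.64 relative to the colon mean and an SD over members of 0.438 (log2), so this may be the source. Ileal tissue in the caecum pool was tested in the same way on 48 genes of the ileum, and their ratio to the L. plantarum ileum array had a median of -4.67 and an SD of 1.54, between the bounds of 1 and 2 set for it, so the test left it open. Colon tissue in the pool, which would bring its pancreas transcripts along, needed Hoxb13 at 2.84, where -0.26 was measured, a shortfall of 1.57 below that level with the floor in its place, but Hoxb13 varied between colon arrays with an SD of 1.05, and 1 gene does not decide it. Over all probe sets this array had Spearman correlations of 0.957 to 0.958 with the colon arrays and 0.959 with each other caecum array. The other caecum arrays had 0.941 to 0.944 with the colon arrays. With the ileum arrays it had 0.932 to 0.934, against 0.914 to 0.923 for the other caecum arrays. The source of this was not tested, and it bears on every comparison with this array. An effect of L. plantarum on the caecum was not tested and stays open, because 1 pool stood for the inoculation.

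The second pattern was the higher level of lymphocyte transcripts in the A. muciniphila colon array. A constant scaling offset between both colon arrays cannot produce the shift of a list, because the random lists share it and it is removed with them. B cell markers shifted by 1.07 and plasma cell markers by -0.03 (SD over members 0.62). The spiked controls of both arrays, whose added amounts were not tested, differed by 0.00186. A lower share of epithelium and muscle would raise all other cell types alike, and the B and plasma cell lists differed by 1.10. But immunoglobulin kappa genes were lower in this pool in every segment, so plasma cells may have differed on their own, and this gap does not decide. Enteric neuron markers shifted by -0.08 and smooth muscle markers by -0.06, while fibroblast markers were higher. These lists went different ways, so they do not decide on such a change either. More lymphoid tissue in the colon pool, such as a lymphoid follicle in the pieces taken, stays open, because the value computed for it, 16 of 20 B and T cell list members past the expression minimum (80%) at least 1.5-fold higher, restates the pattern. An immune response to A. muciniphila would raise the same genes and was not tested.

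The last pattern was the lower level of Dbp and other clock genes in both colonised pools. A different phase of the daily clock would lower the set of 12 early genes and raise the set of 5 late genes, and this held for 5 of the 6 comparisons with germ-free arrays, the exception being the L. plantarum caecum with medians of -0.29 and -0.13, which left it open. A departure of the germ-free pool alone stays open, because the medians of the early set differed between the colonised pools by 0.204 to 0.279 of the smaller difference from germ-free in all 3 segments, but 7, 6 and 8 of its 12 genes were lower with A. muciniphila than with L. plantarum and the others higher, so that these medians do not decide. The time of sampling was not used here, and an effect of colonisation on the clock was not tested.

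For ileum against colon 2358 genes were called, for caecum against colon 1803 and for ileum against caecum 2940, and the highest number for any other split of the 6 arrays was 0 in each. The real split was thus 1 of 10 with as many genes, and 10 splits are too few for a share under 0.05. Every other split also put arrays of both segments in each group, so that the segment differences widened the spread and few calls could be made. Only some of these splits kept 1 array of each pool in each group. The splits therefore cannot decide.

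Other lists stood apart in opposite directions in different segments under the same comparison, and the differences between segments were not tested, because each rests on a pair of arrays per segment. Epithelial defence genes with A. muciniphila against germ-free shifted by 0.12 in the caecum and -0.18 in the ileum, a difference of 0.29. With L. plantarum against germ-free, B cell markers shifted by 0.25 in the colon and -0.58 in the ileum, a difference of 0.83. MHC class II genes shifted by 0.39 and -0.23 in the same segments, a difference of 0.62. Cell cycle genes shifted by 0.09 in the colon and -0.17 in the ileum, a difference of 0.26. Nutrient transporter genes shifted by 0.15 in the caecum and -0.13 in the colon with L. plantarum against germ-free, a difference of 0.27, and by -0.15 and 0.17 with A. muciniphila against L. plantarum, a difference of 0.32. Adipocyte markers with A. muciniphila shifted by 0.38 in the colon and -1.04 in the ileum against germ-free, a difference of 1.42, and by 0.13 and -2.05 against L. plantarum, a difference of 2.18. Pancreas markers with A. muciniphila against germ-free shifted by 0.56 in the colon and -0.44 in the caecum, a difference of 1.00, but the list medians in the caecum, 0.32 and 0.20, were both under the floor and the caecum call was lost with a floor (-0.11) and with the mean of all probe sets (-0.22). Calls were also lost under an alternative for epithelial defence genes in the caecum, MHC class II genes in the ileum, cell cycle genes in both segments, nutrient transporter genes in the colon and adipocyte markers in the colon against L. plantarum.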

How the results depend on the processing

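Scaling to the spiked controls, leaving out the L. plantarum caecum array, agreement over ileum and colon only, and counts without genes 8-fold higher in another segment were tests chosen after seeing the data, and the other alternatives were planned. Counts are given for ileum, caecum and colon in this order, and the cause of a change was not tested unless stated.

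The number of genes at least 2-fold apart changed by less than 1.5 times in 42 of 90 recomputations. With the mean of all probe sets it was 186, 364 and 190 for A. muciniphila against germ-free, 318, 402 and 195 for L. plantarum against germ-free, and 248, 414 and 177 for A. muciniphila against L. plantarum. Without an expression minimum more genes were compared, and the numbers were 2583, 2777 and 2289, then 2753, 2889 and 2394, then 2607, 2869 and 2270. With the 75th percentile as minimum fewer genes were compared, and the numbers were 6, 7 and 15, then 36, 27 and 11, then 25, 43 and 11. A threshold of 1.5-fold, which is less strict, gave 124, 401 and 234, then 658, 526 and 274, then 351, 939 and 210, and 3-fold, which is stricter, gave 7, 6 and 14, then 18, 40 and 6, then 28, 47 and 13. For A. muciniphila against germ-free in the caecum quantile normalisation gave 35 and scaling to the spiked controls 30. For L. plantarum against germ-free in the caecum, leaving out genes 8-fold higher in another segment gave 58.

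The number of genes that differed the same way in all segments was 5, 10 and 12 for the same comparisons. Over ileum and colon only, which asks for agreement in fewer segments, it was 11, 32 and 30, with the mean of all probe sets it was 12, 30 and 22, and after quantile normalisation it was 6 for L. plantarum against germ-free. The correlation between caecum and colon for A. muciniphila against germ-free was 0.139 with the mean of all probe sets, and the other 59 of 60 recomputed correlations stayed within 0.1. The 12 correlations scaled to the spiked controls could not change, because a constant per array does not alter a correlation.

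The number of lists that stood apart stayed within 1.5 times in all 54 recomputations. Equal gene medians and scaling to the spiked controls take a constant from each array, which the random lists share. The 9 recomputations with each of these scalings were thus fixed in advance. Of 641 recomputed list shifts, 584 kept their direction and call, 54 kept their direction but lost the call, and 3 changed direction. The 584 include 107 shifts with each of these 2 scalings, which could not change. The 3 that changed direction are named next. Those were enteroendocrine markers in the colon (-0.038) and large intestine markers in the ileum (-0.081) with a floor, both for A. muciniphila against L. plantarum, and tolerance genes in the caecum for A. muciniphila against germ-free with members above the median only (-0.10).

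Of 615 recomputed differences of named genes, 578 stayed the same, 31 moved and 6 changed direction with the mean of all probe sets. For A. muciniphila against germ-free these were Kcnip2 (-0.13) and Ehd2 (-0.23) in the ileum, Dock10 in the caecum (-0.010), and Igk in the ileum (0.21) and caecum (0.93), and for L. plantarum against germ-free Angptl4 in the colon (-0.61).

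The number of genes called between segments stayed within 1.5 times in 36 of 42 recomputations. Tested on genes above the median only, which are fewer, it was 918 for ileum against colon, 711 for caecum against colon and 1261 for ileum against caecum, and without a minimum difference, which admits smaller changes, it was 5651, 7249 and 7624. Leaving out 1 pool at a time gave 1879 to 2219, 1222 to 2121 and 2288 to 3010. Without the L. plantarum caecum array it was 2394, 1955 and 3057, of which 2340, 1498 and 2563 were shared with all 9 arrays. Of 659 recomputed calls of named genes, 650 stayed, 5 were lost and 4 were gained, the latter all for Aqp8 between caecum and colon. The number of arrays, not the depth of a count, limited all of these values.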

Other observations

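The values below were examined after the results were seen, and no tests of an explanation were made on them.

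In the ileum 4 genes of the large intestine differed in the order germ-free, A. muciniphila, L. plantarum. Car1 was at 10.9, 9.08 and -4.29, Cyp2c55 at 7.10, 4.96 and -0.09, and Saa1 at 8.17, 6.18 and 2.85. Car2 was at 6.68, 4.86 and 3.12. Car1 and Cyp2c55 were under the floor of 1.26 with L. plantarum, and the values of Saa1 and Car2 there were within the range of the Y-linked genes. Aqp8 and Slc37a2 were at 2.86 and 3.56 in the germ-free ileum and under the floor with either bacterium, so that they give no order between the bacteria. The distance of the ileum pieces from the caecum was not tested, and if it differed between the pools these genes would differ without any effect of the bacteria, so this stays open. Large intestine markers as a list shifted by 0.32 with A. muciniphila against L. plantarum in the ileum, but by -0.08 with a floor and 0.01 with the mean of all probe sets.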
